A study of Caenorhabditis elegans with 4 samples.

How the data were processed

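The series is a chromatin immunoprecipitation and sequencing (ChIP-seq) experiment on LSY-2, a C2H2 zinc finger transcription factor of the nematode *Caenorhabditis elegans* that is known for its part in the left-right asymmetry of the ASE taste neurons. Per the labels, hermaphrodites of strain OP240 carried a bombarded lsy-2 transgene fused to GFP and FLAG tags in an unc-119(ed3) background. Per the labels' protocols, synchronized worms were raised at 20 degrees C on bacteria to the second larval stage (L2) and fixed in 2% formaldehyde. Their sonicated chromatin was precipitated with a goat antibody against GFP, and part of each lysate was kept as input DNA. There were 2 ChIP samples and 2 input samples. Samples were grouped by their titles and source names. The free-text descriptions contradict these, since they list ChIP DNA and the antibody under the input samples and input DNA under all 4, and they were not used. The labels do not say whether the replicates came from separate worm cultures, so the spread between them can be technical.

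The files analysed were 3 lists of called regions, 1 for each ChIP sample and 1 combined list. Each region had a chromosome, a start, an end and a q-value that the authors' peak caller had assigned. The caller named in the deposited lists is PeakSeq, a program that scores ChIP read density against a control. How the input samples entered the calling is not given in the sources used here. The genome build was WormBase WS180, per the file headers. The aligner, the caller's version and settings, read filters, read totals and the way the replicates were combined are not given in the sources used here. The last column of each deposited list repeated the q-value as text for every region (1702 of 1702 in the combined list). No list held overlapping regions, and the smallest gap between neighbouring regions was 200 bp in the combined list. The largest q-value was 2.32e-04 in the combined list, 1.94e-04 in replicate 1 and 1.72e-04 in replicate 2. The lists hold no counts of reads, so the depth is unknown and no error could be attached to the strength of a single region. A q-value depends on depth as well as on enrichment, so −log10 q was used to rank regions within a list. Ratios of −log10 q between lists describe the lists and not binding, and the one that was tested compares chromosomes within the same lists.

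Gene names were not attached to regions. The gene table at hand is of assembly WBcel235, which is not the build of the lists, and coordinates were neither mixed nor converted between builds. The planned comparisons of genomic class, divergent promoters, gene biotypes, gene lists, sequence words and score by class, and the look-up of the lsy-2 and unc-119 loci, were therefore not made. The rule for items named in the text, the 20 combined regions of smallest q that overlapped a region in both replicate lists, was applied to the regions alone, and its gene-based parts were not applied. Other regions given by position were chosen after their values were seen. Chromosome lengths of build WS180 were also not used here. Each chromosome was taken as the span from the first to the last base of any region in the 3 lists, so expected shares rest on the span and not on the full length.

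All calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Regions of 2 lists were called shared when they overlapped by at least 1 bp. The number of shared regions was compared with 1000 random placements of the other list within its own chromosomes (one-sided permutation test, smallest possible p = 0.001). Differences of median −log10 q and correlations between replicates used 100000 resamples (two-sided permutation tests, smallest possible p = 1e-05). The correlations of width with −log10 q in the combined list used 10000. Regions per chromosome were compared with the share of the summed span by an exact two-sided binomial test, adjusted by Benjamini-Hochberg over 6 chromosomes. Intervals are 95% exact Clopper-Pearson intervals of a share of regions. They and the p-values treat regions as independent, cover counting error only, and describe these libraries. With 2 ChIP libraries and no values per library for a region outside its own list, no test across samples was made. Alternatives were a 50% reciprocal overlap, midpoints, stronger regions only, lists of equal length, each replicate list in place of the combined list, merging of regions under 1000 bp apart, rotated lists, permuted 500 kb bins, the span of the combined list alone and leaving out chromosome I. The last 4 were added after the data were seen. The overlap, composition, score and chromosome tests and the other alternatives were fixed before the data were examined. The use of spans, the split of each replicate list by strength and the correlations with width were chosen later.

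The code was tested on simulated data. With 400 replicate 2 regions planted on replicate 1 regions, 402 of 1099 regions were found to overlap. Of 50 random lists, 1 reached p = 0.05 or less in the permutation test of overlap. Among 200 uniform lists of 1702 regions, 8 gave a call for any chromosome, and all 200 lists with chromosome III raised 1.5 times gave a call for it.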

Results

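LSY-2 binding was mapped in second larval stage worms that carry LSY-2 fused to GFP, with 2 ChIP samples and 2 input samples. The question, as the labels state it, was where LSY-2 sits on the genome in the living animal. The ChIP replicate 1 list held 1099 regions that cover 598 kb, the replicate 2 list held 746 regions that cover 381 kb, and the combined list held 1702 regions that cover 991 kb, or 1.001% of the chromosome spans. Median region width was 432 bp in replicate 1, 409 bp in replicate 2 and 459 bp in the combined list. No list of the input samples was analysed here, so no comparison of ChIP with input is given. Read totals are unknown, and all positions are in build WS180.

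The strongest LSY-2 region in all 3 lists lay on chromosome V at 11763181 to 11765562, with a −log10 q of 282 in the combined list, 244 in replicate 1 and 204 in replicate 2. It was followed by a region on chromosome IV at 4748305 to 4750793, with a −log10 q of 229, and by one on chromosome III at 12904548 to 12907171, with 198. The 20 strongest combined regions found in both replicates had −log10 q values from 143 to 282 and widths from 709 to 3191 bp, with a median of 1302 bp. Chromosome III held 7 of them, IV held 5, II held 3, I and X held 2 each, and V held 1. In 20 of 20 the q-value was smaller in replicate 1 than in replicate 2, with −log10 q from 111 to 244 in replicate 1 and from 63.8 to 204 in replicate 2.

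The other 6 of these regions on chromosome III began at 3866825, 4474749, 8903767, 9764846, 12978165 and 13462574, and their −log10 q values were 186, 184, 143, 159, 147 and 150. The region at 3866825 to 3870015 was the widest of the 20 at 3191 bp, and it differed least between the replicates, with a −log10 q of 176 in replicate 1 and 171 in replicate 2. On chromosome IV the others began at 654321, 1093776, 3049846 and 8430697, with −log10 q values of 170, 189, 183 and 168. The 3 regions on chromosome II began at 3076640, 8184860 and 10868439, with 190, 143 and 152. On chromosome I they began at 9163217 and 9619631, with 148 and 166, and on X at 14525257 and 15840907, with 159 and 150. The X region at 14525257 to 14526386 had the lowest replicate 2 value of the 20, with a −log10 q of 63.8 against 113 in replicate 1.

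Nearly all replicate 2 regions were also replicate 1 regions. Of the 746 regions of replicate 2, 703 overlapped a replicate 1 region (94.2%, 95% interval 92.3 to 95.8%), and of the 1099 regions of replicate 1, 703 overlapped a replicate 2 region (63.97%, 61.0 to 66.8%). Random placement of the other list gave a mean of 9.44 and 9.41 overlapping regions and at most 21 in either direction (permutation test, one-sided, p = 0.001 for both, the smallest that 1000 placements can give). The shared sequence amounted to 338090 bp, which was 88.8% of the bases of replicate 2 and 56.5% of those of replicate 1. No region had the same start and end in both lists.

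Whether a replicate 1 region was found again depended on its strength. All of the strongest 275 regions of replicate 1, with a −log10 q of 15.6 or more, were also called in replicate 2 (100%, 95% interval 98.7 to 100%). The share was 84.7% (79.9 to 88.8%) in the next 275 regions, 50.7% (44.6 to 56.8%) in the next 274 and 20.4% (15.8 to 25.6%) in the weakest 275. Among replicate 2 regions the share found in replicate 1 fell from 100% (98.0 to 100%) in the strongest 186 to 81.2% (74.8 to 86.5%) in the weakest 186. Replicate 1 regions called in both lists had a median −log10 q of 11.3 against 4.82 for the 396 called in replicate 1 only (permutation test, adjusted p = 1.33e-05 over 4 comparisons). In replicate 2 the medians were 7.44 for shared regions and 4.36 for the 43 single ones (permutation test, adjusted p = 0.0375). The strongest region of replicate 1 with no partner lay on chromosome I at 11517036 to 11517727, with a −log10 q of 13.1. The strongest of replicate 2 lay on X at 2087583 to 2090969, with 8.40, and it was 3387 bp wide and absent from the combined list as well. Whether it lies at the lsy-2 locus, which the transgene also carries, was not determined here.

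Among regions called in both replicate lists, the order by q was similar. Regions with no partner have no value in the other list and are left out. Across 709 overlapping pairs of regions, −log10 q of replicate 1 and replicate 2 had a Spearman rho of 0.87 and a Pearson r of 0.93 (permutation tests, p = 1e-05 for each, the smallest that the resamples can give). Without the 2 pairs farthest from the replicate 1 median, r was 0.92. For log10 width of the same pairs, rho was 0.83 and r was 0.84 (permutation tests, p = 1e-05 for each), and Benjamini-Hochberg adjustment over these 4 correlations leaves each p at 1e-05. The correlations are across regions, which are not independent replicates. The q-value was smaller in replicate 1 in 637 of the 709 pairs (89.8%), and the median ratio of −log10 q of replicate 1 to replicate 2 was 1.39. A q-value depends on the depth of its list, so this ratio is no measure of a change in binding.

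**Figure D1:**
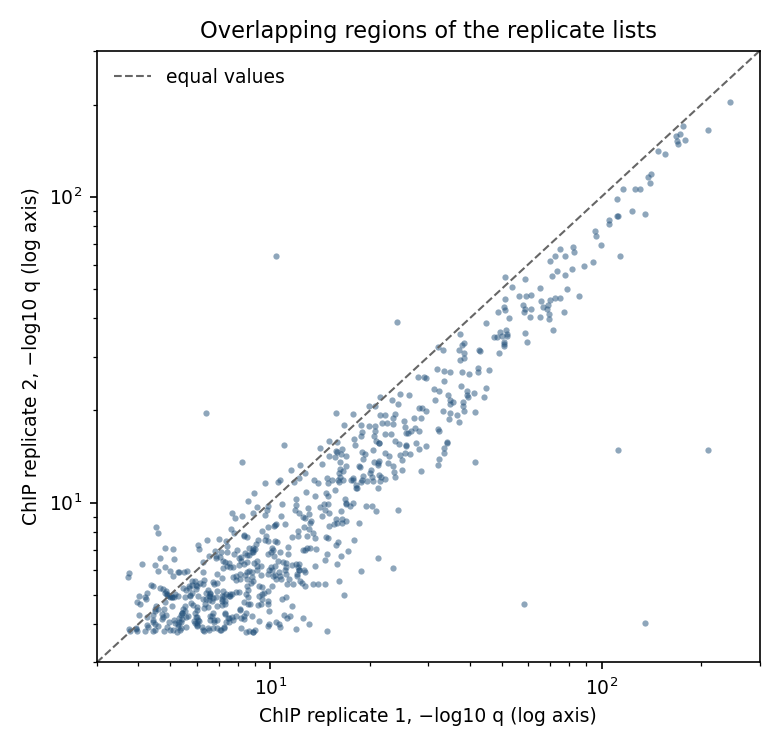
Each point is 1 of 709 overlapping pairs of regions, with −log10 q in ChIP replicate 1 on the horizontal and in ChIP replicate 2 on the vertical log axis, and the dashed line marks equal values. Most points, 637 of 709, lie below the line, and a region that overlaps more than 1 region of the other list gives a point for each.

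In the combined list, 693 of 1702 regions were also called in both replicates (40.7%, 95% interval 38.4 to 43.1%), 375 in replicate 1 only (22.03%, 20.1 to 24.1%), 40 in replicate 2 only (2.35%, 1.68 to 3.19%) and 594 in neither (34.9%, 32.6 to 37.2%). The regions of both replicates were the strong ones, with a median −log10 q of 19.3 and a median width of 523 bp. Regions of 1 replicate had a median −log10 q of 7.26 and regions of neither 4.69 (permutation tests, adjusted p = 1.33e-05 for both steps). The combined list also holds nearly all regions of both replicates, so its values are not independent of the replicate calls and these p-values are no separate evidence. Among the 693 regions of both replicates the combined q-value was smaller than either replicate's in 684, and their median ratio to the stronger replicate was 1.58 in −log10 q. The combined list held 98.2% of replicate 1 regions and 99.5% of replicate 2 regions. Chromosome I carried 133 of the 594 regions of neither replicate, and outside chromosome I the share of regions in neither was 32.4% and in both 42.6%.

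The widest combined region, on chromosome V at 6222834 to 6230075, measured 7242 bp and had a −log10 q of 81.0 in the combined list, 41.6 in replicate 1 and 19.8 in replicate 2. Other wide regions lay on chromosome II at 11633885 to 11637824 (3940 bp, −log10 q of 29.5) and on chromosome I at 9378648 to 9382112 (3465 bp, −log10 q of 32.5), and both were called in both replicates. Across the combined list, log10 width and −log10 q were correlated, with a Spearman rho of 0.43 and a Pearson r of 0.44 (permutation tests across regions, p = 1e-04 for each, the smallest that 10000 resamples can give). The caller set both the limits and the q-value of a region, so the correlation can follow from the calling itself.

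LSY-2 regions, as called, were not spread over the chromosomes in proportion to their span. The expected numbers assume an equal chance at every base of the span. Whether the calling, for instance scaling of ChIP against input by chromosome, shaped the ratios below was not tested. Chromosome III held 351 of the 1702 combined regions, 25.9 per Mb and 1.51 times the number its span would give (95% interval 1.37 to 1.65, exact binomial test, adjusted p = 2.80e-14). Chromosome V held 260 regions, 12.5 per Mb and 0.73 times its expected number (0.65 to 0.81, adjusted p = 5.20e-09, exact binomial test). The X chromosome held 234, 13.6 per Mb and 0.79 times (0.70 to 0.89, adjusted p = 1.10e-04, exact binomial test). For chromosomes II and IV the ratios were 1.07 (0.96 to 1.19) and 1.004 (0.90 to 1.11), and neither passed the exact binomial test (adjusted p = 0.256 and 0.923).

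The same directions for III, V and X were found in each replicate list. The combined list holds nearly all regions of both replicates, so these tests are not independent of those on the combined list. The ratio for chromosome III was 1.57 in replicate 1 and 1.68 in replicate 2, that for V was 0.73 and 0.69, and that for X was 0.77 and 0.70, all with an adjusted p of 9.11e-04 or less in the exact binomial test. When counts per 500 kb bin were permuted, which keeps neighbouring regions together, the adjusted p was 6.00e-05 for III, 3.00e-04 for V and 0.0105 for X (permutation test). Chromosome I changed side with the list. Its ratio was 1.09 (0.97 to 1.21, adjusted p = 0.206, exact binomial test) in the combined list, 0.87 (0.75 to 1.01, adjusted p = 0.0932) in replicate 1 and 0.80 (0.65 to 0.97, adjusted p = 0.0260) in replicate 2. In the stronger 50% of the combined list it was 1.20 and passed above 1 (adjusted p = 0.0254, exact binomial test). That 50% was picked by combined q, and combined −log10 q relative to the replicates was higher on chromosome I, as given among the other observations. Chromosome I held 13.5% and 13.1% of the stronger 50% of the replicate 1 and replicate 2 lists, against 15.2% of the span. The call above 1 is therefore no separate evidence of an excess of strong regions on chromosome I. Chromosome II passed the same exact binomial test in replicate 2, with a ratio of 1.22 (adjusted p = 0.0166), and among the combined regions of both replicates, with 1.21 (adjusted p = 0.0305), but not in replicate 1, with 1.14 (adjusted p = 0.0669).

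**Figure D2:**
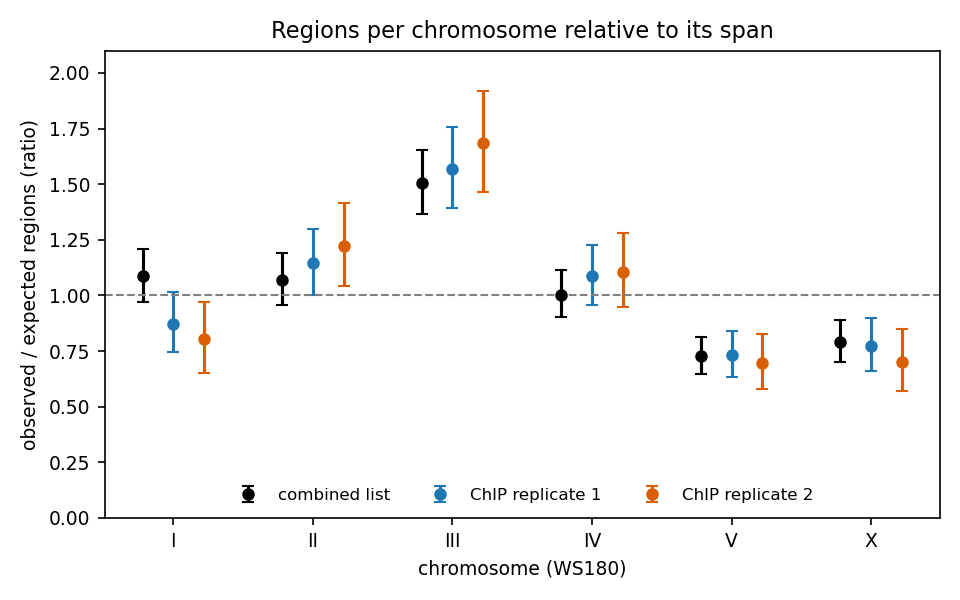
Observed number of regions on each chromosome divided by the number its share of the summed span would give, for the combined list and both ChIP replicate lists, with 95% exact binomial intervals as bars and a dashed line at equality. Chromosome III lies above the line and V and X below it in all 3 lists, while chromosome I is at 1.09 in the combined list and at 0.87 and 0.80 in the replicate lists.

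**Figure D3:**
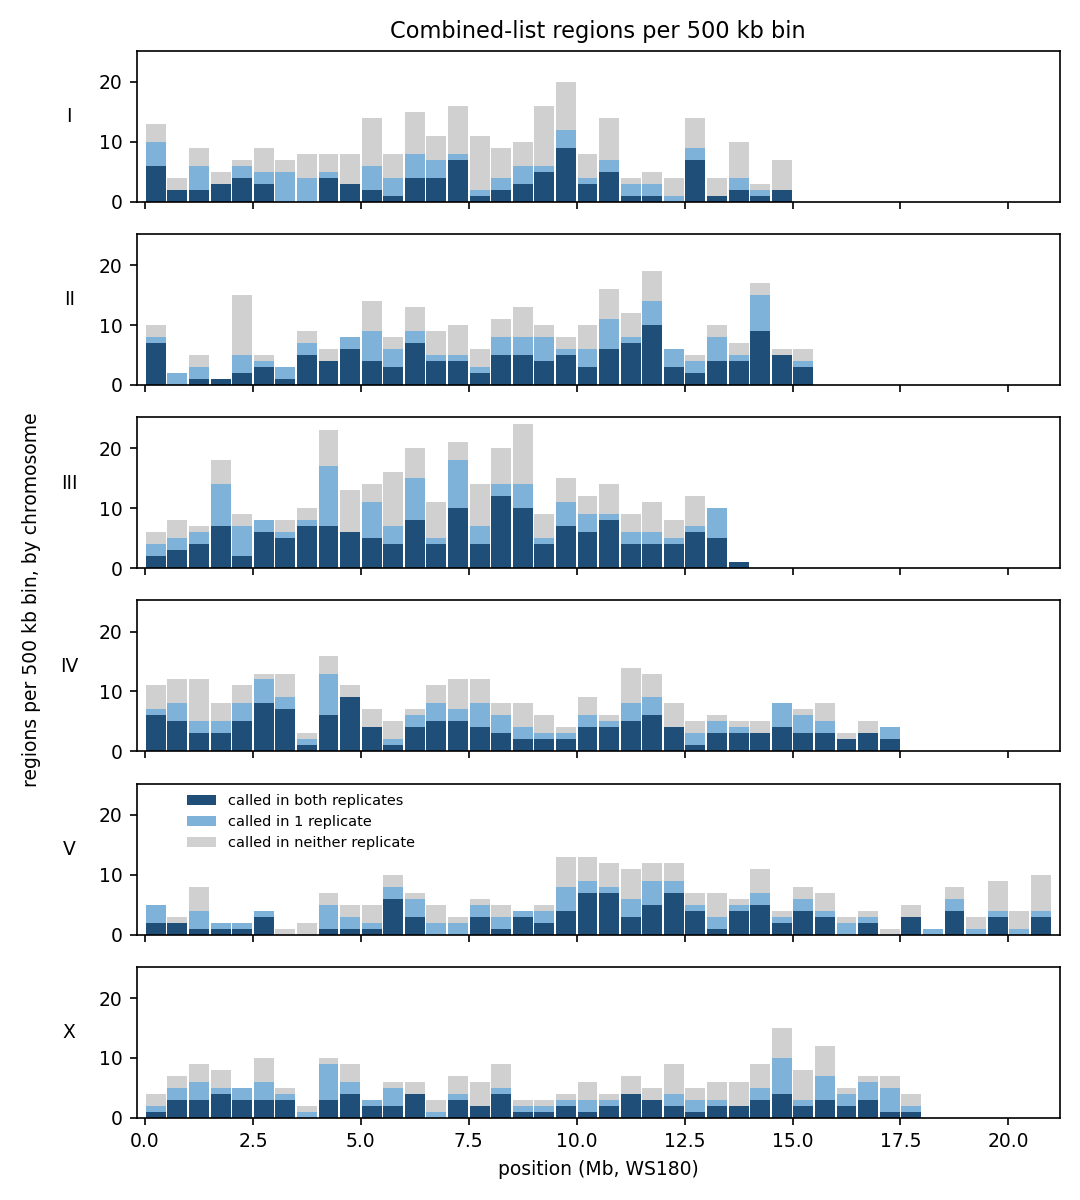
Number of combined-list regions per 500 kb bin along each chromosome (position in Mb, build WS180), stacked by whether the region was also called in both replicates, in 1 or in neither. With full bins counted from the start of each span, chromosome III has the highest mean, 12.96 regions, and chromosome V the lowest, 6.10.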

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

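The tests in this part were chosen after the data were seen. A region near the right end of chromosome I was called in both replicate lists and is missing from the combined list. It spanned 15063996 to 15067646 in replicate 1, with a −log10 q of 15.72, and 15064007 to 15067637 in replicate 2, with a −log10 q of 14.07. It was the only region of either replicate list beyond the last combined region on that chromosome, which ended at 14945988. It is a signal outside the combined list: 20 regions of replicate 1 and 4 of replicate 2 had no combined partner, and this was the 1 case found in both. The right end of chromosome I is known to carry the tandem array of ribosomal RNA genes. Whether the region lies within the array was not determined here.

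The autosomes and X differed in where their regions lay. In the combined list 40.8% of 1468 autosomal regions (95% exact interval 38.3 to 43.4%) and 26.5% of 234 X regions (20.96 to 32.6%) had their midpoint in the central 33.3% of the span, a difference of 14.31 percentage points (Fisher's exact test, two-sided, p = 2.59e-05). Without chromosome I the difference was 12.9 points (Fisher's exact test, p = 1.57e-04). It was 15.2 points in replicate 1 (Fisher's exact test, p = 3.11e-04) and 8.01 points in replicate 2, which did not pass (Fisher's exact test, p = 0.166). These p-values are not adjusted and treat regions as independent, and whether the replicates differ was not tested. The difference between autosomes and X was also not tested with neighbouring regions kept together. Among single autosomes in the combined list, I, III and V held 46.6%, 43.3% and 44.6% of their regions centrally (exact binomial tests against an even spread, adjusted p of 3.33e-04 or less), and II held 98 of 280 and IV 34.5% (adjusted p = 0.682 and 0.711, exact binomial tests). Of these, V alone passed the exact binomial test in both replicate lists (adjusted p = 0.00345 and 0.00301). The calls for I (adjusted p = 0.0697 and 0.118) and III (0.146 and 0.0871) were lost in both replicate lists by the same exact test. Their central shares stayed above 33.3%, at 41.8% and 42.9% for I and at 38.6% and 41.3% for III. The replicate lists hold fewer regions, so a lost call does not show a change of position.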

How the results depend on the processing

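Rotated lists, permuted 500 kb bins, the span of the combined list alone and leaving out chromosome I were chosen only after the data were seen. Of 64 alternative values, 57 kept their direction and their side of the threshold, among them all 10 for replicate overlap and every one for chromosomes III, IV, V and X. The alternatives largely reuse the same regions, so they are not independent of each other. The share of replicate 1 regions found in replicate 2 ranged from 61.3% to 82.8%, and that of replicate 2 regions found in replicate 1 from 83.2% with lists of equal length to 97.6% in the stronger 50% of each list. A 50% reciprocal overlap moved the share of combined regions found in both replicates to 37.4%, since that rule counts fewer overlaps. The ratio of observed to expected regions on chromosome I was 0.80 to 0.87 with a single replicate list and 0.83 among combined regions of both replicates, against 1.20 in the stronger 50% of the combined list, where it gained a call above 1 (exact binomial test, adjusted p = 0.0254, over all alternatives 0.0254 to 0.410 with permuted bins included). It also passed below 1 with the replicate 2 list (adjusted p = 0.0260, exact binomial test). The stronger 50% was picked by combined q, so its call above 1 cannot be separated from the higher combined −log10 q relative to the replicates on chromosome I. Chromosome I held 133 of the 594 regions of the combined list alone, and explanations for that excess are weighed among the other observations. For chromosome II the ratio was 1.14 to 1.22 with a single replicate list and 1.21 among regions of both replicates, and it passed with the replicate 2 list and among regions of both replicates (exact binomial tests, adjusted p = 0.0166 and 0.0305, over all alternatives 0.0166 to 0.644 with permuted bins included); the cause was not tested. No paired analysis was possible because no values of the input samples were used, so no test between groups was made. The alternatives planned for genomic class, divergent promoters, biotypes, gene lists, sequence words and score by class were not run, since no annotation of build WS180 was used here. Depth is unknown, so a region missing from a list shows only that it was not called there.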

Other observations

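Apart from the tests of 3 explanations for chromosome I, the tests in this part were chosen only after the result was seen. LSY-2 regions stood closer together than regions placed at random with equal chance along their chromosome. Of the 1702 combined regions, 782 had another within 10 kb (45.9%), against a mean of 538 and at most 633 in 1000 random placements within chromosomes (permutation test, one-sided, p = 0.001, the smallest possible). The count was not repeated with regions under 1000 bp apart merged, so neighbours can include parts of the same site. The placements also ignored uneven density along a chromosome, such as the central excess of autosomal regions given below. The test therefore cannot tell clustered binding sites from split calls or from broad differences in density. The densest stretches of up to 100 kb held 11 regions each on chromosome III, at 7122754 to 7208478 with 5 regions of both replicates and at 8794662 to 8889247 with 6. A stretch on III at 1859486 to 1951882 held 10 regions, of which 4 were in both replicates. No stretch on another chromosome held more than 9 regions. One with 9 lay on chromosome I at 5281714 to 5380196, and 0 of its regions were called in both replicates. Ties were settled by chromosome order, so other stretches may also hold 9.

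In 500 kb bins of the combined list, autosomal regions were 1.24 times the number of an even spread in the central 33.3% of the span and X regions 0.82 times (permutation of bins within chromosomes, p = 1e-04, the smallest possible, and p = 0.0403). In the replicate lists, tested by region, X held 34 of its 148 regions centrally in replicate 1 (exact binomial test, adjusted p = 0.0204) and 28 of 91 in replicate 2, which did not pass (adjusted p = 0.789, exact binomial test). In the combined list 14 regions were narrower than every region of replicate 1, and the narrowest measured 6 bp. Of these 14, 13 were in neither replicate list.

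Chromosome I held 133 of the 594 combined regions found in neither replicate (22.4%) but 88 of the 693 found in both (12.7%), and it was the only chromosome for which this contrast passed (Fisher's exact test over 6 chromosomes, adjusted p = 3.30e-05; the next smallest was 0.0700 for II). The 3 strongest regions of neither replicate also lay on chromosome I, with −log10 q of 13.9, 13.1 and 12.1. One local block of up to 1 Mb on the chromosome is argued against, since no 1 Mb window held more than 14.29% of the 133 regions. A broader concentration of these regions along the chromosome was not tested. A shift of combined q values along chromosome I is a candidate explanation: among regions called in all lists, the ratio of combined −log10 q to the sum of both replicates' was 1.12 on chromosome I and 0.93 elsewhere, a difference of 0.187 (95% bootstrap interval 0.119 to 0.256, permutation test, p = 1e-05). What made such a shift, for instance scaling of ChIP against input by chromosome, stays open. Weaker regions on chromosome I would raise its share in the weaker 50% of a replicate list. That share was instead lower than in the stronger 50%, at 13.1% against 13.5% in replicate 1 and 11.3% against 13.1% in replicate 2. Over both lists the difference was −0.99 percentage points (Fisher's exact test, p = 0.532). The direction was opposite to this explanation. The rule set beforehand counted a lower share in both replicate lists as evidence against it, and that was met. A further requirement, absent from that rule, was a difference that passes Fisher's exact test. The difference did not pass, so the test does not decide the explanation. Chromosome I had the highest median −log10 q in replicate 2 (8.92), but in replicate 1 (7.53) III (8.74) and IV (7.94) were higher. No biological explanation was tested.

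The replicate 2 list was shorter than that of replicate 1. Of the strongest 275 regions of replicate 1 all were called in replicate 2, and of the weakest 275, 20.36%, while of the weakest 186 regions of replicate 2, 81.2% were called in replicate 1. The lists hold no read counts, so lower sensitivity in replicate 2 and different weak sites cannot be told apart. No biological explanation was tested, because the labels name no difference between the replicates.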
